A study of Mus musculus with 13 samples.

How the data were processed

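The series measured gene expression in CD8 T cells sorted from the spleens of female B10.H7b mice on day 14 after an injection of male spleen cells. Each of the 13 samples was hybridised to its own Affymetrix mouse array. The deposited values were MAS5 signal intensity values per probe set, linear and 1 per probe set and array. On every array they were scaled so that the mean without the top and bottom 2% of probe sets was the same. The version and settings of MAS5 were not given in the sources used here. Detection calls and background values of the arrays were not used here.

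Samples were grouped by the labels into H7aTet+ (n = 4), HYTet+ (n = 4) and Tet- (n = 5). Per the labels the populations of each mouse were kept apart, but they do not say which numbers belong to 1 mouse, so the samples were treated as unpaired and a replicate block was tried as an alternative. P-values of single genes and of array quality measure the spread between these samples. List p-values from camera, described below, compare the members of a list with other genes. They depend on the correlation assumed between genes, so they do not measure that spread alone. The labels gave no batch.

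The array medians ranged from 35.9 to 83.1, a 2.315-fold range. A rule written before the data were examined kept the deposited scaling only when these medians lay within 1.5-fold of one another, so the arrays were quantile normalised. The 64 control probe sets were set aside, which left 45037. A pseudocount of 13.92, which is 25% of the median of the array medians, was added before the log2 transform. The lowest log2 value possible was 3.8, so the size of a change depends on the pseudocount where a group mean lies near it. A probe set was tested when it lay above its own array's median in at least 4 of the 13 arrays. This kept 29305 probe sets (65.07%), which stood for 13527 genes. Of the probe sets that are not controls, 34945 had 1 gene symbol, 932 had several and 9160 had none, and 34741 symbols were brought up to date through gene identifiers. Only probe sets with 1 symbol were used for genes, and the probe set with the highest mean over the 13 arrays stood for its gene. Other probe sets of a gene did not always change in the same direction.

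A linear model with 1 mean per group was fitted to all 13 arrays with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean signal. The 3 comparisons were H7aTet+ minus Tet-, HYTet+ minus Tet- and H7aTet+ minus HYTet+. Tests were two-sided, and Benjamini-Hochberg adjusted p-values under 0.05 were counted as passing. Fold values were taken from the log2 changes, and errors of log2 changes are standard errors from the model. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

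The comparisons, the lists of genes and the rule for named genes were fixed before the data were examined. The rule named, in each comparison, the 10 genes with the largest rise and the 10 with the largest fall among genes that passed and whose arrays did not overlap between the groups. It added up to 4 members of each list with the smallest p and a short set of T cell genes that were always given. An item of that set is not reported here. Genes outside the rule are named as chosen after their values were seen.

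Gene lists were tested with camera of limma at a preset correlation between genes of 0.01. The 25 lists in 3 comparisons gave 75 tests, adjusted together. The lists were cytotoxic granules and death ligands, cytokines and chemokines, naive and central memory genes, effector differentiation, inhibitory receptors and genes induced by the T cell receptor, NK receptors, S phase, G2 and mitosis, pro-apoptotic and anti-apoptotic genes, glycolysis, oxidative phosphorylation, interferon response, the T cell receptor complex, the proteasome, ribosomal proteins, immediate early and heat shock genes, T cell receptor segments, and markers of B cells, plasma cells, myeloid and dendritic cells, CD4 T cells, red cells, platelets and the Y chromosome. The tests were repeated with a correlation estimated from the data and with fry. Single-value comparisons of array quality used exact two-sided permutation tests.

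The number of arrays limits the precision: the median standard error of a log2 change was 0.559 against Tet- and 0.589 between the tetramer groups. The procedure was tested on simulated data with the spread of these arrays. It recovered 25.4%, 26.9% and 29.9% of probe sets shifted by a log2 change of 2 in the 3 comparisons, in the order above, and 63.6%, 60.6% and 65.2% at a log2 change of 3. At a log2 change of 1 it recovered 2.99%, 1.49% and 2.24%. Of the calls, 6.15%, 4.84% and 1.53% were false. In H7aTet+ minus HYTet+ only, 3% of 500 random lists of 30 genes had a list p under 0.05. All 50 lists shifted by a log2 change of 0.5 were recovered there. Genes were simulated as independent of one another, so this cannot test the list p-values where genes of a list move together.

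Alternatives changed the filter, the pseudocount, the scaling, the use of a replicate block, the arrays in the fit, the variance trend, array weights and the number of probe sets per gene, and left out each array in turn. A fit with the hybridisation controls as a covariate and a fit without the 2 arrays of lowest weight were chosen after seeing the data.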

Results

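The data covered 13 samples of sorted CD8 T cells, each on 1 Affymetrix array. Female B10.H7b mice, which lack the minor histocompatibility antigen H7a, had received spleen cells of B10 males and of B10.H7b males. The cells of B10 males carry both H7a and the male antigen HY, and the cells of B10.H7b males carry HY. On day 14, spleen CD8 T cells were sorted with tetramers, which are labelled complexes of a peptide and an MHC molecule that bind T cells specific for that peptide. There were 4 samples that bound the H7a tetramer (H7aTet+), 4 that bound the HY tetramer (HYTet+) and 5 that bound neither (Tet-). The labels give 8000 to 300000 cells for a tetramer-positive sample, 2000000 to 3000000 for a Tet- sample and a purity of at least 98%. The median signal of an array lay between 35.9 and 83.1. All changes below are log2 changes of normalised signal ± standard error, with 4 arrays for each tetramer group and 5 for Tet-. Adjusted p-values of genes are from limma.

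H7aTet+ cells were compared with Tet- cells to find what marks CD8 T cells that bind the H7a tetramer. Genes of cytotoxic granules and of effector T cells were higher in H7aTet+ cells, and genes of naive T cells were lower. Gzma, a granule protease, rose by 3.44 ± 0.30 (10.8-fold, adjusted p = 5.4e-08). Gzmk, another granzyme, rose by 3.66 ± 0.47 (12.6-fold, adjusted p = 2.7e-05). Satb1, a chromatin organiser of T cells, fell by 2.17 ± 0.30 (adjusted p = 7.1e-05), and Ccr7, the receptor that guides naive cells into lymphoid tissue, fell by 2.52 ± 0.51 (adjusted p = 0.005). In all, 830 of 29305 probe sets passed, 502 higher and 328 lower, and they stood for 259 higher and 210 lower genes.

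Of the 34 measured genes of effector differentiation, 18 rose, 1 fell and 15 did not pass, and adjusted over the list alone 24 rose and 1 fell. The list's median was 1.29 (adjusted p = 8.76e-20, and adjusted p = 0.00421 with an estimated correlation). Ccr2, a chemokine receptor, rose by 2.81, Emp3 by 2.59, Cd48, a surface ligand of Cd244, by 2.54 and Bhlhe40, a transcription factor, by 2.46. The member that fell was Anxa1, which was chosen after its values were seen, at -1.58. Genes of cytotoxic granules and death ligands had a median of 0.756 (adjusted p = 5.22e-09, and adjusted p = 0.0124 with an estimated correlation). Of the 18 measured, 6 rose, 0 fell and 12 did not pass, and 7 rose adjusted over the list alone. They included Fasl, the ligand of Fas, at 2.96 ± 0.38 and Nkg7, a granule membrane protein, at 2.34 ± 0.29. The naive and central memory list had a median of -1.26 (adjusted p = 3.38e-10, and adjusted p = 0.0166 with an estimated correlation). Of its 20 measured genes 10 fell, 0 rose and 10 did not pass, and 12 fell adjusted over the list alone. Il7r, the interleukin 7 receptor, fell by 1.45, Dapl1 fell by 2.98 and Igfbp4 fell by 3.87. Granzymes belong to a family with similar sequences, so their probe sets can bind transcripts of relatives.

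Of 10 NK receptor genes 2 rose in H7aTet+ cells, or 4 adjusted over the list alone, with a median of 1.0 (adjusted p = 0.000134, and adjusted p = 0.0544 with an estimated correlation). Klrc1 rose by 2.88 and Klrd1, its partner in an inhibitory receptor, rose by 1.59. Fcer1g, at 1.51 ± 0.52 (adjusted p = 0.13), was among the 4 adjusted over the list alone. Myeloid cells express Fcer1g and Tyrobp, another member, too, so the list does not stand for NK receptors of T cells alone. Interferon response genes had a median of 0.369 (adjusted p = 0.0112, and adjusted p = 0.26 with an estimated correlation). Of the 30 measured, 2 rose, Ifi27l2a at 1.58 and Gbp3 at 1.26, and 4 rose adjusted over the list alone. S phase genes had a median of -0.461 (adjusted p = 0.023, and adjusted p = 0.47 with an estimated correlation), with 3 of 34 lower: Ung at -1.38, Uhrf1 at -1.86 and Tk1 at -2.14. Adjusted over the list alone, 1 S phase gene rose and 4 fell. Of 15 cytokine and chemokine genes 3 rose, Ifng by 1.59, Ccl4 by 2.30 and Ccl5 by 1.19, 0 fell and 12 did not pass, and 3 rose and 2 fell adjusted over the list alone (median 0.309, adjusted p = 0.336). Casp1, Traf1 and Fyn rose by 2.27, 2.19 and 1.30, and Hspa1b, a heat shock protein, rose by 2.03. Another probe set of Traf1 went the other way without passing. Hmgb2, Tnfaip3 and Atp5j rose by 1.46, 1.06 and 1.04. Of the genes induced by the T cell receptor, Nr4a2 rose by 2.29, and Egr2, Icos and the inhibitory receptor Btla changed by -1.97, -1.35 and -2.43.

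Markers of other cells changed too. The myeloid and dendritic list did not shift as a whole (median 0.670, adjusted p = 0.232), but 8 of its 28 genes were higher and 3 lower, and 14 were higher and 9 lower adjusted over the list alone. Vcam1 and C1qa, a complement component, were higher by 2.95 and 2.76, and S100a9 and Ngp were at -3.18 and -2.79. The mean log2 signal of C1qa in Tet- cells, 4.685, lay near the lowest value possible, 3.8. The largest rises of single genes included Clec4n, a lectin, at 4.18 ± 0.58 (18.1-fold), Igf1, a growth factor, at 3.90, the iron exporter Slc40a1 at 3.38, Adamdec1 at 3.09 and Fcna at 3.03, and Lcn2 was among the largest falls at -2.83. B cell markers had a median of -0.429 (adjusted p = 0.0423, and adjusted p = 0.152 with an estimated correlation), with 1 of 18 lower, or 3 adjusted over the list alone. That gene was Ighm, the heavy chain of IgM, at -2.17, and the light chain segment Igkv8-30 fell by 3.21. Probe sets of immunoglobulin genes can bind transcripts of relatives. Of the other largest changes, Gfra2 and Resf1 rose by 3.71 and 3.02. For each of these 2 genes, 1 of 3 other probe sets went the same way, and it did not pass. Clec1b, which is on the list of platelet markers, rose by 2.73. Tdrp, Mthfd1, Trib2, St6gal1 and Rpl37 changed by -3.45, -3.09, -2.95, -2.84 and -1.48.

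The count of 830 was 1673 without Tet- 3, and 456, 510, 547, 465 and 502 without H7aTet+ 1, H7aTet+ 2, Tet- 1, Tet- 2 and Tet- 4. With the signal of the hybridisation controls as a covariate it was 478, of which 37.9% were higher against 60.5% in the fit reported, and the median of the cytotoxic list was 0.487.

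HYTet+ cells were compared with Tet- cells for the same question on the HY antigen. Effector and cytotoxic genes were again higher than in Tet- cells, and genes of naive cells and of B cells were lower. Gzmk rose by 4.02 ± 0.47 (16.3-fold, adjusted p = 4.6e-06) and Gzma by 2.69 ± 0.30 (6.45-fold, adjusted p = 1.8e-06). Il7r fell by 2.51 ± 0.29 (adjusted p = 3.2e-06), and Ccr9, a receptor for homing to the gut, fell by 3.96 ± 0.37 (adjusted p = 1.4e-07). In all, 959 probe sets passed, 591 higher and 368 lower, and they stood for 290 higher and 231 lower genes.

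Of the 34 effector differentiation genes 16 rose, 1 fell and 17 did not pass, and 23 rose and 2 fell adjusted over the list alone. The median was 1.27 (adjusted p = 1.94e-16, and adjusted p = 0.00634 with an estimated correlation). Ccr2 rose by 3.36, Cd48 by 2.82, Klrg1, a receptor of effector cells, by 2.19 and Eomes, a transcription factor of effector and memory cells, by 1.89. The member that fell was Il2rb, a chain of the interleukin 2 and 15 receptors, at -2.01 ± 0.51. Its mean log2 signal in HYTet+ cells, 4.916, lay near the lowest value possible, 3.8, so the size of this fall depends on the pseudocount. Of the 18 cytotoxic genes 7 rose, 0 fell and 11 did not pass, and 8 rose adjusted over the list alone. Their median was 1.01 (adjusted p = 7.31e-08, and adjusted p = 0.0137 with an estimated correlation). Nkg7 rose by 2.80 ± 0.29 and Fasl by 2.19 ± 0.38. In the naive and central memory list 10 of 20 genes fell, 0 rose and 10 did not pass, and 12 fell adjusted over the list alone. Its median was -1.42 (adjusted p = 2.81e-12, and adjusted p = 0.0126 with an estimated correlation). Dapl1 fell by 4.25, Igfbp4 fell by 4.07, Ccr7 fell by 2.85, Actn1 fell by 2.39 and Satb1 fell by 2.23.

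Of 40 genes of G2 and mitosis 5 rose in HYTet+ cells, or 17 adjusted over the list alone, with a median of 0.983 (adjusted p = 1.35e-08, and adjusted p = 0.204 with an estimated correlation). Aurkb, a mitotic kinase, rose by 2.23, Hmgb2 by 2.23, Nusap1, a spindle protein, by 1.78 and Cks2 by 1.22. NK receptor genes had a median of 0.939 (adjusted p = 0.0154, and adjusted p = 0.204 with an estimated correlation). Of these 10 genes 3 rose, Klrc1 at 2.59, Klre1 at 1.96 and Klrd1 at 1.31, and 5 rose and 1 fell adjusted over the list alone. The interferon response list had a median of 0.276 (adjusted p = 0.0319, and adjusted p = 0.338 with an estimated correlation), with Ifit2 and Gbp3 higher by 2.07 and 1.46, and 3 genes higher adjusted over the list alone. Ribosomal protein genes had a median of -0.433 (adjusted p = 0.00186, and adjusted p = 0.403 with an estimated correlation). Of the 26 measured, 2 fell, Rps15 at -1.70 and Rpl37 at -1.41, and 6 fell adjusted over the list alone. Of 15 cytokine and chemokine genes 4 rose, Ifng, Ccl3, Ccl4 and Ccl5 by 1.80, 1.76, 2.68 and 1.13. Of the others 1 fell, Ltb at -1.39, which was chosen after its values were seen, and 10 did not pass, and the list's median was -0.0456 (adjusted p = 0.187). Casp1 and Apaf1, of the pro-apoptotic list, rose by 2.44 and 1.95, and Traf1 and Tnfaip3, of the anti-apoptotic list, rose by 2.23 and 1.43. Fyn, Sh2d1a and Ptprc, which act in T cell receptor signalling, rose by 1.59, 1.55 and 1.01. Tox, Nr4a2, Ccne2, Atp5j and Trbv1 rose by 1.76, 2.43, 1.86, 1.37 and 1.17. Jun, Atf3 and Ppp1r15a, of the immediate early list, changed by -1.58, -2.09 and -1.81, and Btla changed by -2.22.

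Markers of B cells were lower in HYTet+ than in Tet- cells, with a median of -0.883 (adjusted p = 9.97e-08, and adjusted p = 0.00421 with an estimated correlation). Of the 18 measured 5 fell, or 7 adjusted over the list alone, among them Ighm at -3.65, H2-Aa at -2.74, H2-Ab1 at -2.66 and H2-Eb1 at -2.19. The H2 genes encode chains of MHC class II, which macrophages and dendritic cells express too. Igha, Igkv8-30 and Jchain changed by -4.59, -4.15 and -2.10. The myeloid and dendritic list had a median of -1.13 (adjusted p = 1.76e-07, and adjusted p = 0.201 with an estimated correlation). HYTet+ 4 stood apart from its group, with a mean log2 signal of the list of 8.508 against 8.557 ± 0.255 (SD, n = 5) in Tet-, and without it the median was -1.42. Of the 28 genes 8 fell and 0 rose, and 1 rose and 13 fell adjusted over the list alone. S100a9 fell by 3.12, Lyz1, a lysozyme, fell by 2.81, Ly86 fell by 2.59 and Cst3 fell by 2.25. Of the other largest changes, 6330403K07Rik, Arsb, Depdc1a and Osbpl3 rose by 3.52, 3.13, 2.89 and 2.68, and St6gal1, Naaa, Tdrp and Cnn3 changed by -3.77, -3.50, -3.41 and -3.28.

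The count of 959 was 1501 and 1455 without Tet- 3 and Tet- 5, and 471, 504, 481, 604, 583 and 639 without HYTet+ 1, HYTet+ 2, HYTet+ 3, HYTet+ 4, Tet- 2 and Tet- 4. With the hybridisation controls as a covariate it was 218, of which 35.3% were higher against 61.6%, and the median of the cytotoxic list was 0.432.

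**Figure D1:**
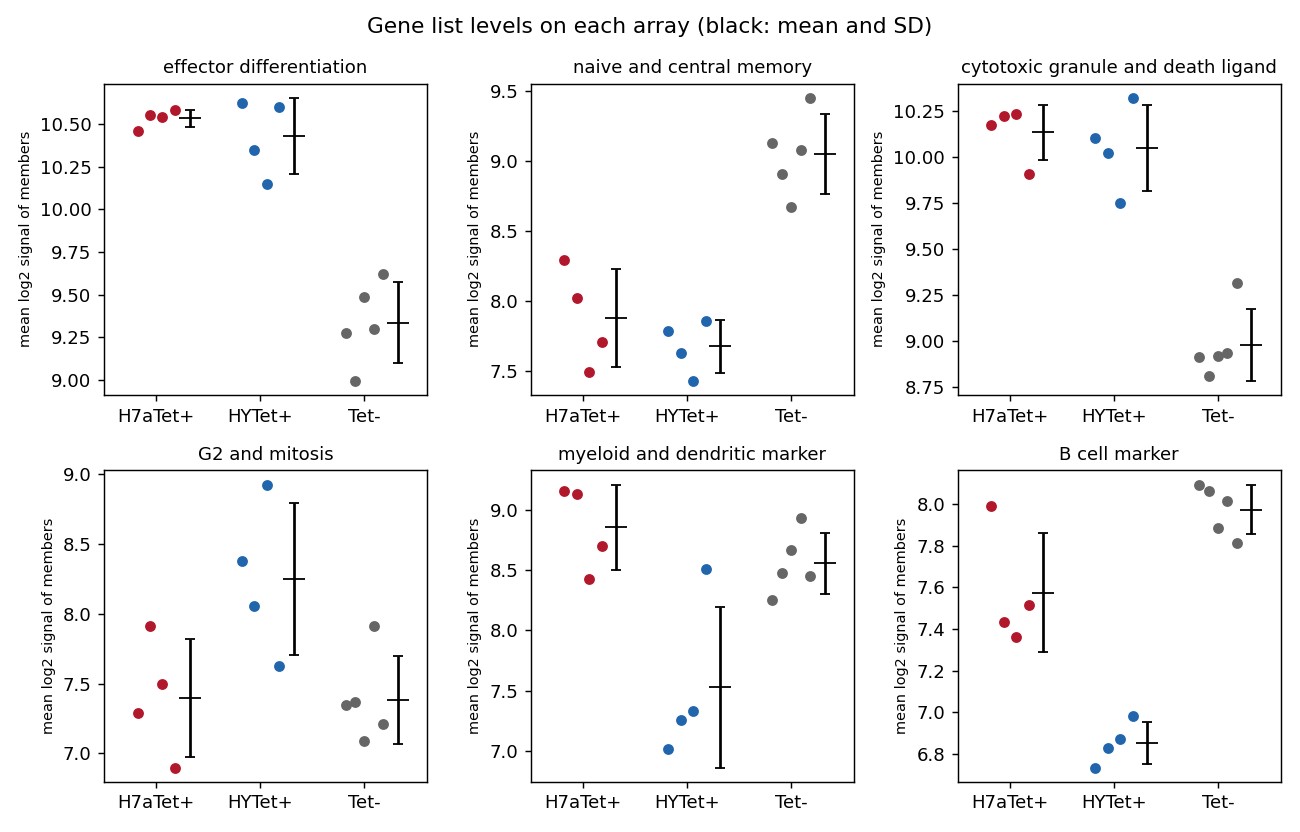
Mean log2 signal of the measured members of 6 gene lists on each of the 13 arrays, with the mean and SD of each group in black. All tetramer-positive arrays lie above all Tet- arrays for effector differentiation and for cytotoxic granules and death ligands, and below them for naive and central memory genes.

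Many of the changes against Tet- cells were called in both tetramer groups. Of the probe sets that passed, 330 were higher in both, 173 were lower in both and 0 went opposite ways. The shared Tet- arrays add to these counts, and how many they would give alone was not tested. Gzma, Gzmk, Fasl, Nkg7, Ccr2 and Cd48 were higher in both tetramer groups, and Dapl1, Igfbp4, Satb1, Ccr7 and Il7r lower in both. Across probe sets the changes correlated at r = 0.697. The same Tet- arrays alone gave r = 0.442 in simulations with no effect. With separate Tet- arrays for each comparison r was 0.298. Each comparison then had fewer Tet- arrays and none in common, so 0.298 cannot be set against 0.442. Probe sets are not independent replicates. Of the 1286 probe sets that passed in either comparison, 9 also passed in the test between the tetramer groups.

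**Figure D2:**
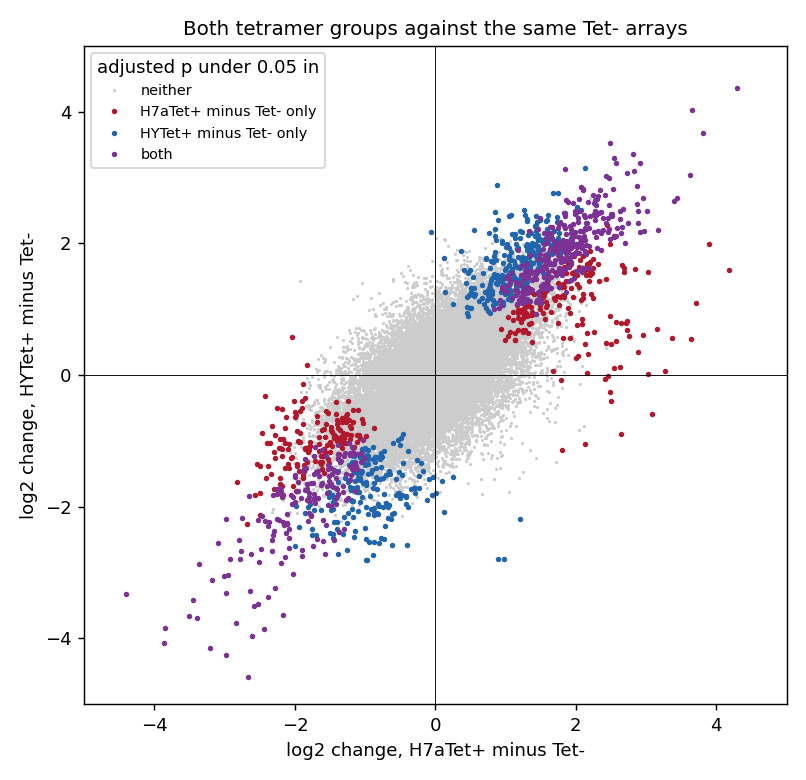
Log2 change of each of 29305 probe sets in H7aTet+ minus Tet- (horizontal) and HYTet+ minus Tet- (vertical), coloured by the comparison in which the adjusted p was under 0.05. The 330 probe sets higher in both lie at the upper right and the 173 lower in both at the lower left.

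H7aTet+ and HYTet+ cells were compared to see whether cells specific for the 2 antigens differed when primed in the same mice. Transcripts known from macrophages were higher in H7aTet+ cells. Adamdec1, a protease, was higher by 3.68 ± 0.60 (12.8-fold, adjusted p = 0.018), Slpi, a protease inhibitor, by 3.53 ± 0.62 (adjusted p = 0.02) and Csf1r, the receptor for macrophage growth factor, by 3.03 ± 0.54 (8.18-fold, adjusted p = 0.02). Clec4a2, Selenop and Lyz1 were higher by 3.18, 1.94 and 1.83. Tox2, a transcription factor related to Tox, was lower by a log2 change of -3.35 ± 0.64 (adjusted p = 0.035). Iglv1, Fcna and Adgre4, which were chosen after their values were seen, were higher by 3.78, 3.02 and 2.76. These were the 10 genes that passed, and with 3 probe sets that have no symbol there were 13 probe sets higher and 1 lower.

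Of the 28 myeloid and dendritic markers 3 were higher, 0 lower and 25 did not pass, and 17 were higher adjusted over the list alone. Their median was 1.58 (adjusted p = 1.54e-22, and adjusted p = 0.0137 with an estimated correlation). HYTet+ 4 stood apart from its group in these transcripts. Its log2 signal of Csf1r was 14.18, inside the range of 14.10 to 14.72 in H7aTet+, while the other HYTet+ arrays lay between 9.81 and 10.76. B cell markers had a median of 0.774 (adjusted p = 1.41e-07, and adjusted p = 0.00421 with an estimated correlation). Of the 18 measured 0 passed the test over all genes, and 4 were higher adjusted over the list alone. These were H2-Aa at 1.86, H2-Eb1 at 1.56, Ighm at 1.48 and H2-Ab1 at 1.41 (adjusted p = 0.06, 0.32, 0.17 and 0.5). Macrophages and dendritic cells express the H2 genes too, so the list does not stand for B cells alone.

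The cell cycle lists differed in the other direction. G2 and mitosis genes had a median of -0.854 (adjusted p = 9.39e-15, and adjusted p = 0.0769 with an estimated correlation), with 35 of 40 genes negative, 0 past the test over all genes and 5 lower adjusted over the list alone. S phase genes had a median of -0.587 (adjusted p = 5.75e-08, and adjusted p = 0.118 with an estimated correlation), with 28 of 34 negative, 0 past the test over all genes and 2 lower adjusted over the list alone. Mki67, a marker of cycling cells, was at -1.01 ± 0.42 (adjusted p = 1.0). The array means of G2 and mitosis genes overlapped, with 7.399 ± 0.422 (SD, n = 4) in H7aTet+ and 8.248 ± 0.547 (SD, n = 4) in HYTet+. Immediate early and heat shock genes had a median of 0.395 (adjusted p = 0.00304, and adjusted p = 0.335 with an estimated correlation), with 1 gene higher adjusted over the list alone. Ribosomal protein genes had a median of 0.157 (adjusted p = 0.027, and adjusted p = 0.528 with an estimated correlation).

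Effector, cytotoxic and naive genes showed no shift between the tetramer groups that passed, with list medians of 0.0636, 0.0597 and 0.262 (adjusted p = 0.554, 0.744 and 0.0887). Adjusted over the list alone, 2 naive and central memory genes were higher, and 0 effector or cytotoxic genes were higher or lower. Gzma was at 0.75 ± 0.31, Klrg1 at -0.87 ± 0.33 and Il7r at 1.07 ± 0.30, and none of these passed (adjusted p = 1.0, 1.0 and 0.48). Il2rb was at 1.62 ± 0.54 (adjusted p = 0.92). Of the 75 list tests in the 3 comparisons 22 passed. With an estimated correlation 9 of these held: effector, cytotoxic and naive genes in both comparisons with Tet-, B cell markers in HYTet+ minus Tet-, and B cell and myeloid markers in H7aTet+ minus HYTet+. With fry, which tests whether the genes of a list move one way without comparing them with other genes, 15 passed.

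The count of 14 probe sets was 0 with limma on the 2 groups alone and 0 without H7aTet+ 1, H7aTet+ 4, HYTet+ 1, HYTet+ 2 or HYTet+ 3, with 1796, 1034, 875, 1022, 974 and 954 at an unadjusted p under 0.05. It was 3, 39, 51, 2, 4, 35 and 9 without H7aTet+ 2, H7aTet+ 3, HYTet+ 4, Tet- 1, Tet- 2, Tet- 3 and Tet- 4, and each of the 10 genes failed under 10 to 18 of 27 other settings. At an unadjusted p under 0.05 there were 1297 probe sets, where 1465 would be expected by chance.

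Several T cell genes did not pass against Tet- cells in the probe set of highest signal. Against Tet- cells, Gzmb was at 1.11 ± 0.44 in H7aTet+ and 1.05 ± 0.44 in HYTet+ cells, and Prf1, perforin, at 0.63 ± 0.57 and 0.08 ± 0.57. Cd44, a marker of antigen experience, was at 0.96 ± 0.33 and 0.61 ± 0.33, and Pdcd1, an inhibitory receptor, at 0.81 ± 0.57 and 1.31 ± 0.57. Cd8a and Cd8b1, the chains of the CD8 coreceptor, were at 0.44 and 0.53 in H7aTet+ and at 0.61 and 0.79 in HYTet+ cells. In H7aTet+ minus Tet-, the 4 other probe sets of Cd8a went the other way without passing. For Bcl2, another of its 5 probe sets passed and was lower in both tetramer groups. Bcl2, Il2ra and Mki67 were at -0.08, -0.35 and 0.15 in H7aTet+ cells and at 0.01, 0.19 and 1.16 in HYTet+ cells. Klrg1 rose by 1.33 ± 0.31 in H7aTet+ cells (adjusted p = 0.014), and Il2rb was at -0.39 ± 0.51 there.

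The control probe sets of the arrays differed between tetramer-positive and Tet- arrays. The mean log2 signal of the hybridisation controls, RNAs added in fixed amounts, was 12.17 ± 0.56 (SD, n = 4) in H7aTet+, 12.16 ± 0.35 (SD, n = 4) in HYTet+ and 13.22 ± 0.61 (SD, n = 5) in Tet- (exact permutation p = 0.0397 and 0.0317, both 0.0893 adjusted over 18 tests). Tet- 5, at 12.24, lay among the tetramer-positive arrays. The 3' to 5' difference of the Actb control, which grows when transcripts are copied incompletely, was 8.32 in H7aTet+, 7.48 in HYTet+ and 5.56 in Tet- (exact permutation p = 0.0317 and 0.0635, adjusted 0.0893 and 0.127). The Actb 3' probe set alone was higher than in Tet- by 2.62 in H7aTet+ and 2.56 in HYTet+, so this cannot be read as incomplete copying alone. For Gapdh the 3' to 5' difference was 6.27, 7.49 and 6.33. It differed between the tetramer groups at an exact permutation p of 0.0286 (adjusted 0.0893), the smallest this design can give, so it goes with the groups in which macrophage and cell cycle transcripts differed. The arrays with the lowest weights were Tet- 3 at 0.371 and H7aTet+ 4 at 0.527, and without both the counts were 1561, 2063 and 27 in the 3 comparisons, a setting chosen after seeing the data.

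**Figure D3:**
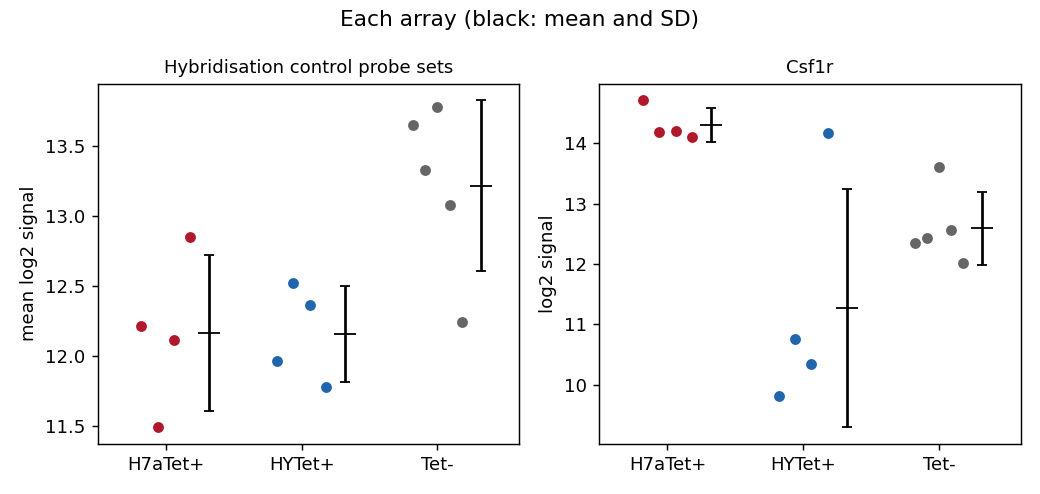
Mean log2 signal of the hybridisation control probe sets (left) and log2 signal of Csf1r (right) on each of the 13 arrays, with the mean and SD of each group in black. Tet- 5 lies at 12.24 among the tetramer-positive arrays on the left, and HYTet+ 4 lies at 14.18 among the H7aTet+ arrays on the right.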

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

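The tests of a wrong label, of dilution, of the trend with the hybridisation controls over all arrays, of Tet- 5 and of B cell and granulocyte RNA were chosen only after the result was seen, as were the bounds they were held to. The bootstrap standard errors below resample the genes of a list, so they do not measure the spread between arrays.

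The myeloid and dendritic list was higher in H7aTet+ than in HYTet+ cells by a median of 1.58, and this difference was tested directly, as were those of Adamdec1 (3.68), Iglv1 (3.78), Slpi (3.53), Csf1r (3.03 and 2.70 in the 2 probe sets that passed), Adgre4 (2.76), Selenop (1.94), Fcna (3.02), Lyz1 (1.83) and Clec4a2 (3.18). Another probe set of Csf1r was higher too but did not pass. RNA from macrophages in the sorted samples is a candidate explanation. A second list of macrophage genes, none of them on the first list, had a median of 0.936 with 23 of 25 positive (camera p = 1.93e-12, and p = 0.00645 with an estimated correlation), though 0 passed over all probe sets. Abundant macrophage genes were at 2.91 for C1qb, 2.35 for Vcam1 and 1.81 for Lyz2, and none of these passed (adjusted p = 0.06, 0.17 and 0.31, limma). Others were at 0.21 for Cd68, 0.47 for Ctss and 0.79 for Cd74. All of these genes but C1qb were chosen after their values were seen. The labels, however, give a sort to at least 98% purity. A wrong label on HYTet+ 4 would bear on every comparison that uses this array. The array's myeloid list mean of 8.508, against 7.021 to 7.329 in the other HYTet+ arrays, narrowed the difference. A wrong label cannot be told apart. The array's position among probe sets lower in H7aTet+ was 0.539 on a scale from 0 at HYTet+ to 1 at H7aTet+. Held-out H7aTet+ arrays spanned 0.0426 to 0.736 and the other HYTet+ arrays 0.169 to 0.33. The array's mean of the B cell list, 6.98, lay nearer to the other HYTet+ arrays (6.734 to 6.869) than to H7aTet+ (7.361 to 7.991). Other lists went the other way. Its G2 and mitosis mean, 7.628, lay within H7aTet+ (6.899 to 7.911) and below the other HYTet+ arrays (8.058 to 8.925). Its immediate early and heat shock mean, 10.88, lay nearer to H7aTet+ (10.53 to 10.87) than to the other HYTet+ arrays (9.882 to 10.2). Array quality cannot be told apart either, because the hybridisation controls as a covariate left the median at 1.58 but moved the changes between these groups by a median of 0.00348 only, and the Gapdh 3' to 5' difference, 6.27 against 7.49 (exact permutation p = 0.0286), goes with the groups and was not used as a covariate. In 1 of the 35 splits of the 8 arrays, the real one, the list's shift was as large (1.58, highest other 1.42). This is the smallest number possible, with no allowance for the choice of this list among 25. Chance is therefore unlikely for this list taken alone but not excluded. A difference between cells of the 2 antigen specificities stays open as untested.

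G2 and mitosis genes differed by -0.854 and S phase genes by -0.587 between H7aTet+ and HYTet+ cells, both tested directly. HYTet+ 4, for which a wrong label could not be told apart, had a G2 and mitosis mean of 7.628, within the range of H7aTet+. Dilution of T cell RNA by RNA of other cells in the H7aTet+ samples would lower all T cell transcripts. The T cell receptor complex list, however, was at -0.0834 (bootstrap standard error 0.0993), against a bound of -0.427, which argues against dilution as the whole cause. Its array means were 9.543 and 9.618 in H7aTet+ 1 and 2 and 10.02 and 10.03 in H7aTet+ 3 and 4, against 9.817 to 10.05 in HYTet+. Other cells express some of its members too, such as Ptpn6 and Vav1. A smaller part of dilution therefore stays open. Array quality cannot be told apart, since the covariate gave -0.844 but moved hardly any change between these groups, and the Gapdh 3' to 5' difference of 6.27 against 7.49 goes with them too. As large a shift came in 2 of 35 splits for G2 and mitosis (0.854 in size, highest other 0.957), so chance cannot be excluded, and in 1 of 35 for S phase (0.587, highest other 0.539), with no allowance for the choice of the list, while the list did not pass with an estimated correlation (adjusted p = 0.118) or with fry (0.0766). A difference in cycling between cells of the 2 antigen specificities stays open as untested.

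Effector genes were higher and naive genes lower in both tetramer groups than in Tet-, whose arrays had higher hybridisation controls. A trend with these controls is argued against as the whole cause for the effector and naive lists only. As a covariate the controls moved other changes by a median of 0.421 and 0.424. The effector list stayed at 1.19 and 1.08 and the naive list at -1.37 and -1.51 (bootstrap standard errors 0.228, 0.2, 0.273 and 0.42). The cytotoxic list, however, fell from 0.756 to 0.487 in H7aTet+ and from 1.01 to 0.432 in HYTet+, so the trend stays open for it. The controls of Tet- 5 lay among the tetramer-positive arrays. Its median position was 0.805 on a scale from 0 at tetramer-positive to 1 at Tet- arrays. That was the lowest of the Tet- arrays, which reached 1.22, and 1 array decides nothing. Dilution of T cell RNA by RNA of B cells and granulocytes in Tet- samples would make naive genes higher in tetramer-positive cells, but their medians were -1.26 and -1.42 (bootstrap standard errors 0.398 and 0.454), although B cell RNA could add to members that B cells express too, such as Ccr7. For effector genes, this dilution as the whole cause would raise the T cell receptor complex list as much. That list, at 0.242 in H7aTet+ and 0.193 in HYTet+, lay below the effector list by 1.05 and 1.08 (bootstrap standard errors 0.306 and 0.285). Its array means overlapped those of Tet- in both comparisons, while the array means of the effector list did not. This argues against dilution as the whole cause in both, with a limit. B cells and granulocytes express some members of the receptor complex list too, such as Ptpn6 and Vav1, and their RNA could hold that list down. A smaller part of dilution in the rise stays open. Amplification from fewer cells goes with the groups and was not tested, and exposure to antigen stays open as the biological explanation.

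As many probe sets passed in 2 of 100 splits of the arrays for H7aTet+ minus Tet- (830, highest other 1068) and in 2 of 100 for HYTet+ minus Tet- (959, highest other 1207). The real split is counted in each, and another split gave more calls than it. Chance is therefore unlikely for both counts but not excluded. The highest other split put 4 of the 5 Tet- arrays on 1 side in each. For H7aTet+ minus HYTet+ it was 3 of 35 (14, highest other 19), so chance cannot be excluded for that count, and the highest other split exchanged H7aTet+ 3 and HYTet+ 4.

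Other lists differed between the tetramer groups by a direct test, and the lists whose splits were counted are those that had differed. B cell markers, among them H2 genes that macrophages express too, differed by 0.774. The shift was as large in 1 of 35 splits (highest other 0.527), with no allowance for the choice of the list. Chance is therefore unlikely for this list taken alone but not excluded. Immediate early and heat shock genes differed by 0.395, as large in 4 of 35 splits (highest other 0.608), and ribosomal protein genes by 0.157, as large in 14 of 35 (highest other 0.381), so chance cannot be excluded for either. Tox2 differed by -3.35.

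The Actb 3' control probe set, which the comparisons did not use, was higher in tetramer-positive than in Tet- arrays by a log2 difference of 2.59.

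In 27 of 381 groups tested an array lay far from the rest of its group, where about 19 would be expected by chance. For means of gene lists these were Tet- 5 in the cytotoxic list at 9.317, H7aTet+ 4 in the pro-apoptotic list at 7.263, H7aTet+ 3 in the ribosomal list at 12.56 and H7aTet+ 2 in the plasma cell list at 6.95. Tet- 5 stood apart at log2 signals of 10.19 for Ccr2, 14.72 for Ifng, 8.63 for Rpl37, 9.02 for Dapl1 and 11.91 for Rps15. HYTet+ 4 did so at 11.45 for Gzmk, 15.73 for Ifng, 15.56 for Ptprc, 11.20 for Rps15 and 10.53 for Adgre4. Tet- 3 did so at 10.88 for Slc40a1, 5.42 for Tk1, 8.08 for Trib2 and 5.12 for Osbpl3. H7aTet+ 4 lay at 4.19 for Igfbp4, 6.65 for Ifit2 and 10.62 for Ppp1r15a. The remaining arrays were HYTet+ 1 at 12.76 for Cd48, HYTet+ 2 at 7.91 for Apaf1 and 10.08 for Ccl3, HYTet+ 3 at 13.83 for Nkg7 and 4.24 for Igfbp4, and Tet- 1 at 6.90 for Tox.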

How the results depend on the processing

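The covariate of the hybridisation controls and the fit without the 2 arrays of lowest weight were chosen after the results were seen. Of the values of the 22 lists that passed, 309 of 352 under other settings and 270 of 286 without 1 array kept their direction and passed, the rest kept their direction only, and none reversed. G2 and mitosis (-0.854) and S phase (-0.587) in H7aTet+ minus HYTet+ did not pass with an estimated correlation (adjusted p = 0.0769 and 0.118) or with fry (0.0654 and 0.0766). Lists that had not passed did so in 16 and 13 values, and changed sign in 64 and 80 while passing in neither fit. The named genes passed under every setting that tested them in 26 of 56 cases for H7aTet+ minus Tet-, 31 of 67 for HYTet+ minus Tet- and 0 of 10 for H7aTet+ minus HYTet+, and the covariate ended 51 of 133 calls. The count of H7aTet+ minus Tet-, 830, was 547 with arrays centred on the median, 467 on the 2 groups alone, 243 without the variance trend, 1324 with array weights, 513 with 1 probe set per gene, 1561 without the 2 arrays and 478 with the covariate. For HYTet+ minus Tet-, 959, it was 295 without the trend, 1938 with weights, 557 with 1 probe set per gene, 2063 without the 2 arrays and 218 with the covariate. For H7aTet+ minus HYTet+, 14, it was 31 without a filter, 31 at the largest pseudocount, 28 with the deposited scaling, 37 with weights, 7 with 1 probe set per gene, 27 without the 2 arrays and 33 with the covariate. With limma it was 0 at a stricter filter, with centred arrays, on the 2 groups alone and without the trend, where 558, 1172, 1796 and 1344 had an unadjusted p under 0.05. Leaving out 1 array gave 456 to 1673, 471 to 1501 and 0 to 51. The correlation of 0.697 was 0.794 at the stricter filter, 0.745 at the largest pseudocount, 0.742 with a fixed replicate block, 0.742 with weights, 0.753 without the 2 arrays, 0.807 with the covariate, 0.298 with separate Tet- arrays and 0.624 to 0.744 without 1 array. A single probe set per gene and the stricter filter test fewer probe sets, and for the other changes the cause was not tested. The median change of all probe sets, 0.0408 and 0.0561 against Tet-, was 0.119 and 0.186 with centred arrays, where 77.9% and 84.5% of the calls were higher, and -0.0644 and -0.134 with the deposited scaling. With a replicate block the counts stayed within 1.5-fold, and the numbers did not pair the arrays: in 12 pairs with the same number the correlation of residuals was -0.157 to 0.0436, and 3 of 13 arrays matched their own number best. Signal over background was not used here, so genes of low signal rest on the filter alone.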

Other observations

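The comparison of the probe sets of Xist was chosen after the result was seen. Of the 25 lists, 14 passed in no comparison, with a lowest adjusted p of 0.0565 for glycolysis in H7aTet+ minus Tet-. Glycolysis genes had medians of -0.561 in H7aTet+ and -0.251 in HYTet+ against Tet-, and 13 and 11 of the 15 measured were negative. Oxidative phosphorylation genes were at 0.160 and -0.0165, and proteasome genes at 0.237 and 0.242. Cytokines and chemokines were at 0.309 and -0.0456, inhibitory receptors and genes induced by the T cell receptor at 0.0601 and 0.156, pro-apoptotic genes at -0.0807 and 0.0681 and anti-apoptotic genes at 0.0766 and 0.120. The T cell receptor complex list was at 0.242 and 0.193, and receptor segments at -0.0603 and 0.128. Between the tetramer groups, these lists had medians of -0.141 for glycolysis, 0.113 for oxidative phosphorylation, 0.0477 for the proteasome, -0.215 for cytokines, -0.205 for inhibitory receptors, -0.167 and -0.298 for pro-apoptotic and anti-apoptotic genes, -0.0834 for the receptor complex and 0.103 for receptor segments. Lists that passed in another comparison were, in H7aTet+ minus Tet-, at -0.0505 for G2 and mitosis, -0.152 for ribosomal proteins and -0.0651 for immediate early and heat shock genes. In HYTet+ minus Tet- they were at 0.0814 for S phase and -0.110 for immediate early and heat shock genes, and between the tetramer groups at 0.282 for NK receptors and -0.0207 for the interferon response. The mean or the test had another sign than the median for inhibitory receptors, receptor segments, red cell markers, G2 and mitosis and immediate early genes in H7aTet+ minus Tet-. The same held for cytokines, oxidative phosphorylation and receptor segments in HYTet+ minus Tet-, and for the interferon response, plasma cell and platelet markers in H7aTet+ minus HYTet+.

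Lists of markers of plasma cells, CD4 T cells, red cells, platelets and male cells passed in no comparison. Plasma cell markers had medians of -0.961 in H7aTet+ and -0.423 in HYTet+ against Tet-, and -0.0408 between the tetramer groups. CD4 T cell markers were at -0.264, 0.439 and -0.184, red cell markers at -0.0146, 0.0783 and -0.332, and platelet markers at 0.0479, 0.228 and -0.314 in the same order. The 2 measured Y-linked genes, which stand for cells of the male donors, had medians of -0.106, -0.905 and 0.799. Xist, expressed from the inactive X chromosome of female cells, was higher by 2.29 in H7aTet+ and by 2.47 in HYTet+ than in Tet- cells (adjusted p = 0.00048 and 0.00013, limma) in the probe set with the highest signal. A probe set of Xist with a mean signal close to it was at -0.91 and -0.44 (adjusted p = 0.24 and 0.66), and the last at 0.86 and 0.56, so the probe sets of Xist did not move together.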
